A study of Mus musculus with 4 samples.

How the data were processed

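The labels describe Lin-cKit+ cells purified from mouse bone marrow (C57BL/6 per the labels) on a cell sorter, and libraries made with the 10x Genomics Chromium 3' kit, version 3.1. The series lists 2 wild-type and 2 Phf6 R274X Tg mice, 1 library each, and each library was treated as 1 replicate of its genotype. Per the submitters' processing notes, reads were processed with Cell Ranger (version not given in the sources used here) on mm10. The deposited values are raw UMI counts for 32285 genes in filtered barcodes, and the values checked here were whole numbers. Of the gene identifiers, 32158 (99.6%) matched GENCODE M21, which gave positions and gene types. Reads were not analysed here, so neither the labelled mutation nor the alignment was checked.

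The libraries WT 1, WT 2, Tg 1 and Tg 2 held 112939221, 126309664, 145142803 and 164673775 UMIs, with medians of 12356, 13523, 15176 and 15339 UMIs per barcode. Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrially encoded UMIs. Over that last limit were 20.1, 16.0, 9.68 and 6.22% of barcodes, with median depths of 1335, 1369, 1824 and 1281 UMIs. Of 34728 barcodes 29856 passed. Scrublet, as in scanpy 1.11.5 with seed 0, called 97, 138, 2 and 5 doublets with its own threshold, which failed to separate a doublet group in both Tg libraries. The highest scores were removed instead, 0.8% of barcodes per 1000 barcodes of the library, which took out 320, 373, 457 and 669 barcodes and left 28037 cells.

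Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes over the libraries were taken, leaving out the S phase, G2M, histone, sex chromosome, ribosomal protein and mitochondrial lists and Phf6. Clusters came from 30 principal components, 20 exact nearest neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1, seed 0) without integration of libraries, which gave 22 clusters. The neighbour distances were made exact after a first pass had given clusters that changed between runs; results had been seen by then. A cluster took the class with the most markers among its top 10 genes, given at least 2 such markers and at least 3 markers of the class detected; this naming rule was set after the clusters were seen, and the marker lists before. Clusters of the same name were merged. Class names end in "like" because they rest on transcripts alone. The adjusted Rand index was 0.726 between clusterings with seeds 0 and 1, and 0.567 between the clustering used and one with components centred per library.

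UMI counts were summed per library over all kept cells and over each class with at least 50 cells in every library, which left 7 classes. Sums were compared, Tg minus WT, with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood fit) and Benjamini-Hochberg adjustment over genes at 0.05. The 2 against 2 design leaves 2 residual degrees of freedom per gene, which the tool pools across genes. CPM values are counts over the library's or class's total. Class shares were compared with edgeR's quasi-likelihood test on cell numbers without an abundance trend, with the kept cells as library size. The interaction used sums of the stem-multipotent-like and granulocyte-progenitor-like classes with library, class and class by genotype terms. The 25 gene lists and the marker lists (13 over all cells) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry.

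Named genes were Phf6 and, among genes with adjusted p under 0.05, at least 10 CPM in 1 group and both Tg libraries beyond both WT libraries, the 10 largest rises and falls for all cells and for stem-multipotent-like cells and the 3 largest in other classes. Up to 4 members per list were chosen by p. Predicted genes without a curated symbol and sex chromosome genes were counted but not named. Some genes that met these rules are not reported here. Groups, comparisons, gene and marker lists, cell filters, naming rule for genes and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, library totals without TMM, no expression filter, the replicate number as a block, leaving out each library, no doublet removal, stricter cells (2000 UMIs, 1000 genes, 5% mitochondrial), thinned depth, equal class shares (4957 cells per library), Leiden resolutions 0.6 and 1.5, and centred components. Added after the data were seen were classes after centring, clusters without the 4199 genes that moved over 2-fold in any class, another clustering seed, stem-multipotent-like cells without the cycling cluster, and cluster 7 alone.

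Precision was tested on simulated counts with known changes. Counts per library were drawn from a negative binomial distribution, and cells were not resampled. All genes had the same dispersion and were drawn independently. Class counts were also drawn at a fixed dispersion. Recovery and false calls may therefore look better than they would in these libraries. In the gene simulations 100 genes were changed at each fold size, as many raised as lowered. In the data 6480 of 15503 genes were called over all cells. Scaling and false calls under so broad a change were not tested. edgeR found 72% of 1.5-fold and 88% of 2-fold changes over all cells with 9 false calls among 15429 genes, and 55% and 82% in the stem-multipotent-like class with 5 among 12849. DESeq2 found 60% and 72% over all cells, and 36% and 66% in that class. The interaction test found 30% and 63% with 2 false calls among 14097. Camera found 1 of 1 altered list with the preset correlation and 0 of 1 with an estimated correlation, and fry found 1 of 1. The class count test found 1 of 2 altered classes at 1.5-fold and 2 of 2 at 2-fold, with 0 false calls among 10 classes. Cell numbers of WT libraries differed by 3.36 times the chi-square expected of sampling and those of Tg libraries by 5.53 times, and gene levels by 2.17 and 6.83 times the noise of sampling cells. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and blastn 2.17.0. Splits of samples into other groups were not counted, since groups of 2 are too small for that.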

Results

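Sorted Lin-cKit+ bone marrow cells of 2 wild-type mice and 2 mice labelled Phf6 R274X Tg (called Tg here) were compared by single-cell RNA sequencing from the 3' end. The libraries WT 1, WT 2, Tg 1 and Tg 2 held 8177, 8249, 8431 and 9871 barcodes and 112939221, 126309664, 145142803 and 164673775 UMIs. After filtering, 6006, 6459, 7098 and 8474 cells remained, with median depths of 15361.5, 15673, 16337 and 15846 UMIs per cell. The comparisons asked how high the Phf6 transcript was, which genes and gene lists differed over all cells, which cell classes differed in share, which genes differed within each class, and whether the difference was the same in stem-like and granulocyte-progenitor-like cells. Each library was the unit of every test. The p-values measure the spread between these samples, and the series design gives 2 mice per genotype. Genotype was the label that separated the groups, so any difference in handling, batch or strain background between the mice is part of each difference reported.

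Phf6 encodes a nuclear PHD-finger protein that binds the nucleosome remodelling and deacetylase complex and is mutated in human leukaemia. Its transcript was higher in Tg cells: 31.9 and 31.0 CPM (counts scaled to the library total) in WT 1 and WT 2, and 105 and 81.5 CPM in Tg 1 and Tg 2. The group means were 31.5 ± 0.635 and 93.3 ± 16.7 CPM (mean ± SD, n = 2 mice each), a log2 difference of 1.58 (SE 0.09, edgeR adjusted p = 5.2e-07). Phf6 rose in each of the 7 cell classes tested. The rise was 0.83 in granulocyte-progenitor-like cells (21.9 to 39.6 CPM), 1.19 in monocyte-like cells (26.3 to 60.8 CPM) and 1.36 in lymphoid-progenitor-like cells (45.7 to 111 CPM). It was 1.963 in megakaryocyte-like cells (48.9 to 191 CPM), 2.11 in stem-multipotent-like cells (40.6 to 166 CPM), 2.13 in erythroid-like cells (37.8 to 175 CPM) and 2.72 in basophil-mast-like cells (39.7 to 265 CPM). Reads from the 3' end do not show the labelled mutation, and the transcript level says nothing about it. The labels used here do not say whether Tg stands for extra Phf6 copies or for a changed gene of the mouse itself, and transcripts of either were counted together.

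**Figure D1:**
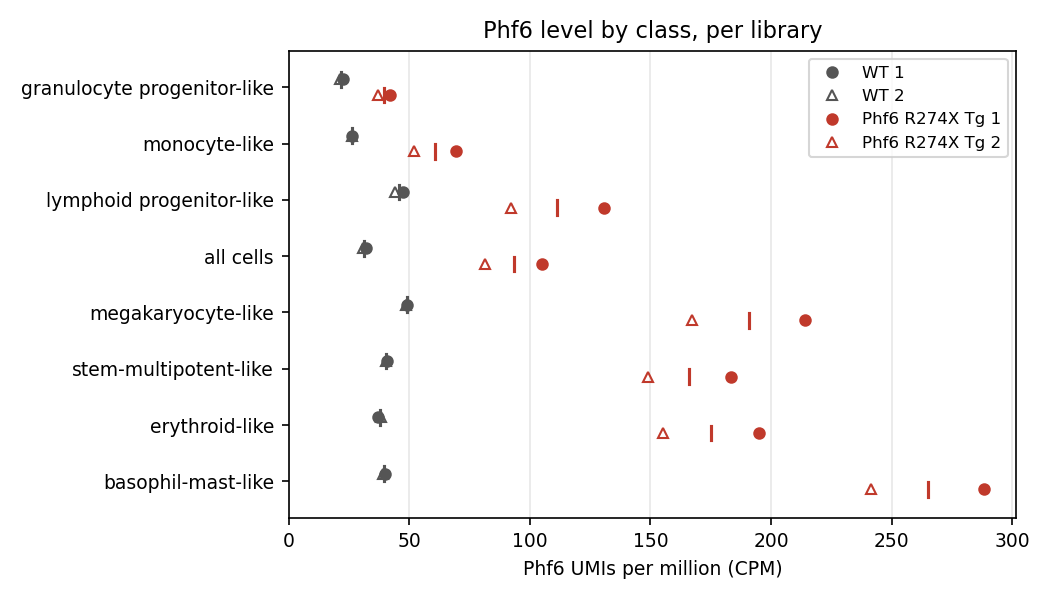
Phf6 transcript level in CPM (horizontal axis) in each cell class and in all cells (vertical axis), with a circle and a triangle for the 2 libraries of each genotype and a short line at each group mean. In stem-multipotent-like cells the group means were 40.6 CPM in WT and 166 CPM in Tg.

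Over all cells, the calprotectin subunit gene S100a8 fell from 1596 ± 161 to 126 ± 26.8 CPM (log2 -3.64, SE 0.17). Fcnb, which encodes the neutrophil granule lectin ficolin-B, fell from 55.1 to 4.85 CPM (-3.49, SE 0.11). The inducible chaperone genes Hspa1a (0.529 to 22.9 CPM, 5.45, SE 0.10) and Hspa1b (1.15 to 23.01 CPM, 4.34, SE 0.12) rose. So did Trbc1, a constant region of the T-cell receptor beta chain (1.46 to 51.5 CPM, 5.16, SE 0.10). Thy1, a lymphoid and progenitor surface protein, rose by 2.64, the eosinophil peroxidase gene Epx by 2.59 and the cytokine-signal inhibitor Socs3 by 2.36. Also higher were the interleukin-3 receptor gene Csf2rb2 (2.32) and the lipopolysaccharide co-receptor gene Cd14 (2.27). BC004004 rose from 55.9 to 268 CPM (2.28) and Hddc3, a nucleotide hydrolase gene, from 4.29 to 20.2 CPM (2.26). Falls were also seen for the sulfotransferase gene Sult1a1 (-2.48), the GTPase gene Gimap6 (-2.32), the integrin gene Itga1 (-2.22), the adhesion gene Vcam1 (39.8 to 9.29 CPM, -2.08) and the lectin receptor gene Clec4a2 (41.3 to 10.6 CPM, -1.94). The chemokine gene Ccl5 fell (-2.34), but stood at 0.041 when every library was given the same share of each class. The genes Hspa1a and Hspa1b are near-identical copies of each other, as are Trbc1 and Trbc2 and Csf2rb2 and Csf2rb, so the split of reads between such copies is uncertain. For the genes named in this comparison by size of change, edgeR adjusted p lay between 2.0e-10 and 1.7e-07.

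The antisense transcript BC023719 had 3488 UMIs in WT and 2 in Tg cells, a ratio of 2237 (95% counting interval 619 to 18483). Asb17os, also antisense, fell from 16.1 to 2.62 CPM (-2.61). Both are reported as uncertain because reads of the opposite strand or an overlapping gene were not separated here. The neutrophil elastase gene Elane fell from 6372 to 3998 CPM (-0.65, edgeR adjusted p = 0.0024), while the myeloperoxidase gene Mpo stood at 4821 and 4650 CPM (-0.030, edgeR adjusted p = 0.85). edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p called 6480 of 15503 genes, 3233 higher and 3247 lower in Tg. Of these, 397 rose and 997 fell more than 2-fold. The 2 WT and 2 Tg values did not overlap for 70.4% of tested genes, where chance gives 33.3%. Sums over all cells mix classes of different share. With equal class shares 7016 genes passed.

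Interferon-response genes were lower in Tg cells: Iigp1 (-1.79), Ifi204 (-1.79), Ifi209 (-1.74), Oas1g (-1.69) and Ifi44 (-1.60), while Ifitm3 (0.48) and Gbp3 (0.29) rose. Of 43 measured members 2 rose and 30 fell (2 and 30 adjusted over the list alone). The median was -0.46 (camera adjusted p = 4.1e-10, or 0.72 with an estimated correlation). Ifi202b, an interferon-inducible gene outside the list, had 0 UMIs in WT and 705 and 858 in Tg 1 and Tg 2. C57BL/6 mice do not express it, so a strain difference was not separated from the falls in this list. Replication-dependent histone transcripts, which are made in S phase and mostly lack poly(A) tails, fell for 13 of 16 and rose for 0 (0 and 13 over the list alone). Hist1h2ab stood at -1.67, Hist1h3c at -1.23 and Hist1h4c at -1.21 (median -0.68, camera adjusted p = 1.6e-07, or 0.72 with an estimated correlation). Heat shock and unfolded protein response genes rose for 11 of 25 and fell for 0 (11 and 0 over the list alone). The glutathione-degrading enzyme gene Chac1 stood at 1.21 and the endoplasmic reticulum chaperone genes Sdf2l1 at 0.65 and Calr at 0.55 (median 0.17, camera adjusted p = 1.6e-07, or 0.72 with an estimated correlation). The haemoglobin genes Hba-a2 (-2.06), Hbb-bs (-1.73) and Hba-a1 (-1.52) and the heme enzyme gene Cpox (-0.95) fell, while Alad (1.58) and the transferrin receptor gene Tfrc (0.81) rose. Alad rose over 2-fold in all 7 classes and is among the 23 such genes taken up below, none of which is called an effect of the Phf6 label. The heme and haemoglobin list had 2 rises and 9 falls among 17 (2 and 10 over the list alone, median -0.34, camera adjusted p = 0.0015, or 0.72 with an estimated correlation). Hba-a1 and Hba-a2 are near-identical copies.

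Glycolysis genes rose: the glucose transporter gene Slc2a1 (1.03), Ldha (0.89), Pkm (0.67) and Gapdh (0.64), with falls of Pfkm (-0.39) and Hk2 (-0.21). The list had 11 rises and 2 falls among 16 (11 and 2 over the list alone, median 0.53, camera adjusted p = 0.0041, or 0.72 with an estimated correlation). Among cholesterol and fatty acid synthesis genes, Elovl6 (0.62) and Fdps (0.53) rose and the desaturase gene Scd1 fell (-1.65). The list had 14 rises and 1 fall among 23 (15 and 2 over the list alone, median 0.21, camera adjusted p = 0.010, or 0.83 with an estimated correlation). Ribosome biogenesis genes rose for 14 of 38 and fell for 0 (14 and 0 over the list alone). Nle1 (0.67), Bop1 (0.53) and Mrto4 (0.53) led (median 0.17, camera adjusted p = 0.013, or 0.93 with an estimated correlation). Genes of stem cell quiescence and self-renewal fell: Fgd5 (-1.67), Ndn (-1.31), Mllt3 (-1.27), Gfi1b (-1.12) and Slamf1 (-0.96). There were rises of Hoxa7 (0.75), Hoxa9 (0.61) and the cell-cycle inhibitor gene Cdkn1a (0.49). That list had 3 rises and 12 falls among 30 (3 and 12 over the list alone, median -0.14, camera adjusted p = 0.023, or 0.97 with an estimated correlation). With fry, histones (adjusted p = 0.053), glycolysis (0.051), ribosome biogenesis (0.10) and quiescence genes (0.11) did not pass.

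The other 17 lists did not pass camera over all cells. Rises and falls, with those adjusted over the list alone in brackets, were 10 and 3 of 41 for S phase (9 and 3, camera adjusted p = 0.65), 4 and 6 of 51 for G2M phase (4 and 6, adjusted p = 0.91), 6 and 9 of 26 for leukaemia-associated factors (6 and 10, adjusted p = 0.87) and 6 and 9 of 77 for ribosomal proteins (5 and 5, adjusted p = 0.87). They were 0 and 3 of 13 for mitochondrially encoded transcripts (0 and 0, adjusted p = 0.26), 10 and 3 of 74 for oxidative phosphorylation (5 and 1, adjusted p = 0.45), 5 and 11 of 25 for immediate early genes (6 and 13, adjusted p = 0.91) and 5 and 1 of 21 for the nucleosome remodelling complex and Phf6 partners (5 and 1, adjusted p = 0.37). For Polycomb and histone methylation they were 5 and 6 of 38 (4 and 5, adjusted p = 0.91), for primary granule proteins 4 and 2 of 13 (4 and 2, adjusted p = 0.45), for secondary granule and mature neutrophil genes 5 and 3 of 15 (5 and 3, adjusted p = 0.16) and for platelet genes 6 and 6 of 23 (6 and 6, adjusted p = 0.91). Median, mean and test differed in sign for inflammatory genes (7 and 9 of 25, 7 and 9 over the list alone, median -0.02, mean 0.12, tested upward, adjusted p = 0.38) and cytokine receptor targets (9 and 8 of 26, 10 and 8, median -0.00, mean 0.21, upward, adjusted p = 0.090). They also differed for p53 targets (6 and 7 of 26, 6 and 7, median and mean below 0, upward, adjusted p = 0.91), antigen presentation (4 and 4 of 19, 4 and 4, median 0.11, mean -0.08, downward, adjusted p = 0.91) and lymphoid priming (4 and 4 of 19, 5 and 5, median -0.27, mean -0.31, upward, adjusted p = 0.91).

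Marker genes of several cell types also differed over all cells. Erythroid markers fell for 38 of 45 and rose for 2 (median -1.21, camera adjusted p = 8.7e-56, or 0.20 with an estimated correlation). Among them were the erythroid transcription factor genes Klf1 (36.3 to 12.4 CPM, -1.53) and Gata1 (25.4 to 13.8 CPM, -0.85). Macrophage markers fell for 12 of 12 (median -1.66, camera adjusted p = 3.9e-12, or 0.21 with an estimated correlation), including the complement gene C1qa, at 0.681 CPM in WT. Falls also led among stem (6 rises, 17 falls of 29, camera adjusted p = 1.4e-06, or 0.30 with an estimated correlation), T-NK (3 rises and 11 falls of 16, adjusted p = 0.0012, or 0.21 with an estimated correlation), granulocyte (5 and 8 of 29, adjusted p = 0.0027, or 0.65 with an estimated correlation) and dendritic markers (4 and 12 of 21, adjusted p = 0.0038, or 0.30 with an estimated correlation). Basophil-mast markers rose for 13 of 19 and fell for 2 (median 0.48, camera adjusted p = 1.4e-06, or 0.21 with an estimated correlation). The basophil protease gene Mcpt8 stood at 65.5 and 122 CPM. Eosinophil markers rose for 4 of 10 and fell for 1 (median 0.71, camera adjusted p = 1.5e-04, or 0.30 with an estimated correlation). Stroma (0 and 2 of 4, camera adjusted p = 0.065), monocyte (6 and 11 of 23, adjusted p = 0.072), lymphoid (3 and 3 of 11, adjusted p = 0.78), B-lineage (1 and 2 of 14, adjusted p = 0.14) and megakaryocyte markers (6 and 7 of 25, adjusted p = 0.78, median 0.04, mean -0.06) did not pass. Adjusted over the list alone, the counts of the 13 marker lists were the same except for erythroid (2 and 39), basophil-mast (13 and 3), eosinophil (5 and 1), lymphoid (3 and 4) and megakaryocyte markers (7 and 7).

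Stem-multipotent-like cells, named by genes such as Hlf and Mecom, made up 10.2 ± 0.259% of WT and 23.1 ± 1.22% of Tg cells of the Lin-cKit+ sort (log2 1.18, SE 0.11, edgeR adjusted p = 2.2e-09). The rise was 0.39 with components centred per library, 0.60 with no doublet removal and 0.85 with stricter cells. The markers that name the class went the other way: over all cells Hlf fell from 65.1 to 40.7 CPM (-0.66) and Mecom from 17.9 to 12.7 CPM (-0.49), and within the class 27 of 29 stem markers fell and 1 rose (1 and 27 over the list alone, median -1.78, camera adjusted p = 2.5e-43, or 0.13 with an estimated correlation). Lymphoid-progenitor-like cells, the precursors of B and T cells, fell from 10.2 ± 0.587% to 1.91 ± 0.421% (-2.43, edgeR adjusted p = 6.6e-13). That fall was -0.99 with centred components, -3.78 with no doublet removal and -3.46 with stricter cells. Over all cells the lymphoid markers did not fall as a set (3 rises and 3 falls of 11, camera adjusted p = 0.78). Dntt stood at 24.9 CPM in WT and 25.2 CPM in Tg (0.04) and Flt3 rose (0.86), while Il7r (-0.95) and Cd7 (-1.02) fell. Erythroid-like cells fell from 11.4 ± 0.362% to 6.44 ± 0.551% (-0.83, adjusted p = 1.0e-06) and monocyte-like cells from 16.997 ± 0.726% to 12.5 ± 1.25% (-0.45, adjusted p = 5.1e-04). The monocyte-like call was lost with TMM factors over classes (-0.19, adjusted p = 0.10) and without WT 2 (-0.40, adjusted p = 0.075). Basophil-mast-like cells rose from 2.82 ± 0.105% to 4.54 ± 0.213% (0.68, adjusted p = 1.3e-04) and eosinophil-like cells from 0.430 ± 0.114% to 1.15 ± 0.119% (1.42, adjusted p = 3.3e-05). T-NK-innate lymphoid-like cells numbered 42 and 41 in the WT libraries and 2 and 1 in the Tg libraries (0.667 ± 0.0456% to 0.0200 ± 0.0116%, log2 -4.99, adjusted p = 4.7e-08).

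Dendritic-like cells stood at 0.869 ± 0.113% and 0.565 ± 0.00205% (-0.62, edgeR adjusted p = 0.028). That call was lost with the replicate number as a block (adjusted p = 0.091), at resolution 0.6 (0.12), with centred components (0.11), with TMM factors over classes (0.15) and without any 1 library (0.075 to 0.26). Granulocyte-progenitor-like cells (28.2 ± 0.592% and 24.9 ± 2.35%, log2 -0.18, edgeR adjusted p = 0.090) and megakaryocyte-like cells (5.61 ± 0.256% and 4.94 ± 0.400%, log2 -0.19, edgeR adjusted p = 0.15) did not pass. In other clusterings and cell filters megakaryocyte-like cells passed as higher: 0.93 with no doublet removal, 0.92 with another seed, 0.65 with stricter cells, 0.30 and 0.31 at resolutions 0.6 and 1.5 and 0.26 with centred components. Granulocyte-progenitor-like cells passed as lower with centred components (-0.62), at resolutions 0.6 (-0.44) and 1.5 (-0.15), with another seed (-0.28) and without Tg 2 (-0.28). The remaining 5 clusters had no class by the naming rule and held 12.5% of WT and 19.97% of Tg cells. Shares sum to 100%, so a rise of one class lowers the others, and an exact permutation test of 2 against 2 libraries cannot go below a p of 0.3333.

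Because genes that differ by genotype also shape clusters, the clusters were made again without the 4199 genes that moved more than 2-fold in any class. Each new cluster took the class that most of its cells had in the first clustering, so the names are not independent of it. Stem-multipotent-like cells then differed by 0.23 (edgeR adjusted p = 0.16), lymphoid-progenitor-like cells by -0.69 (0.0070) and eosinophil-like cells by -0.29 (0.72). Erythroid-like (-0.59, edgeR adjusted p = 0.0031), monocyte-like (-0.76, adjusted p = 3.4e-04), basophil-mast-like (0.59, adjusted p = 0.0050) and T-NK-like cells (-3.69, adjusted p = 1.1e-09) again passed in the same direction. Dendritic-like (-0.33, edgeR adjusted p = 0.16), granulocyte-progenitor-like (-0.35, adjusted p = 0.0501) and megakaryocyte-like cells (0.33, adjusted p = 0.064) did not pass.

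**Figure D2:**
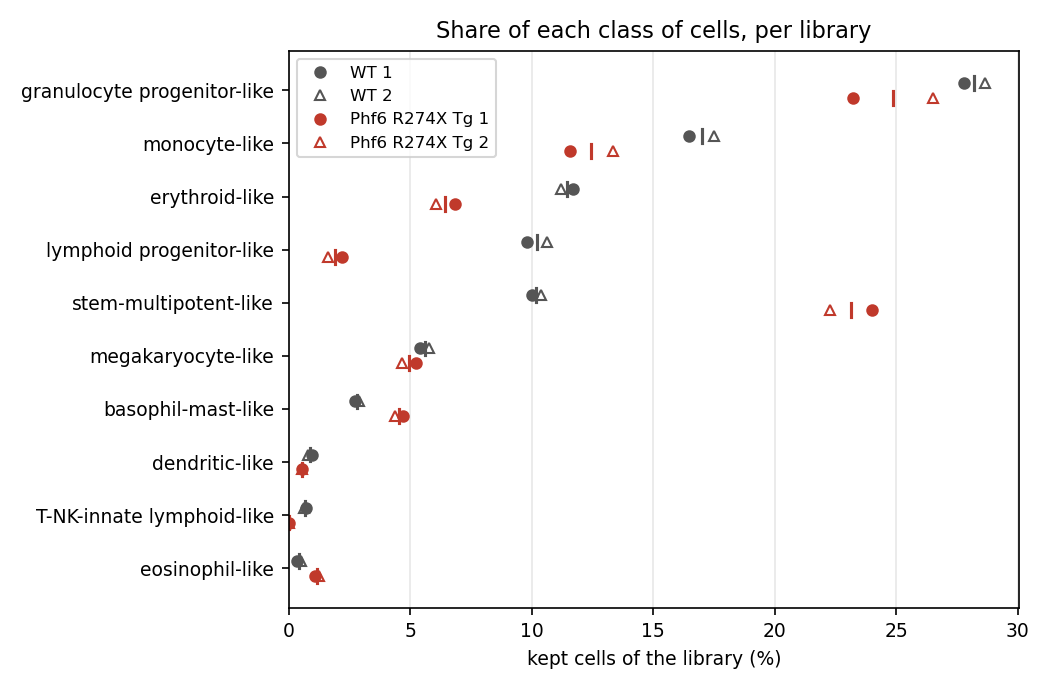
Percent of the kept cells of a library (horizontal axis) in each cell class (vertical axis), with a circle and a triangle for the 2 libraries of each genotype and a short line at each group mean. Stem-multipotent-like cells averaged 10.2% in WT and 23.1% in Tg, and lymphoid-progenitor-like cells 10.2% and 1.91%.

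Within stem-multipotent-like cells, Cd48 and Cd244a, surface proteins of the SLAM family that mark multipotent progenitors rather than long-term stem cells, rose from 24.7 to 187 CPM (log2 2.9998, SE 0.11) and from 5.16 to 43.2 CPM (3.15, SE 0.16). The long-term stem cell markers Slamf1 (-3.62), Fgd5 (-2.78), Mllt3 (-2.88), Mecom (-1.82), Procr (-1.78) and Hlf (-1.75) fell. Replication genes such as Uhrf1 (2.35, SE 0.11), Rrm2 (2.45), Ung (2.48), Tyms (2.03) and Mcm5 (1.94) rose, and the growth-factor response genes Egr3 (-6.67), Nr4a2 (-3.42) and Nr4a1 (-3.03) fell. The genotypes filled different clusters of the class: 87.2 and 89.4% of WT cells were in cluster 7, against 74.7 and 79.8% of Tg cells in cluster 0. Values within cluster 7 alone, which held 524 of 601, 599 of 670, 247 of 1703 and 208 of 1887 class cells of WT 1, WT 2, Tg 1 and Tg 2, are therefore given beside those of the class for many genes and lists.

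Phf6 rose by 3.19 in cluster 7 (36.3 to 348 CPM) against 2.11 in the class. Trbc1 had 2 UMIs in WT and 7685 in Tg stem-multipotent-like cells (ratio 1094, interval 303 to 9033). In cluster 7 alone it had 2 and 84. Trbc2 had 2 and 686 (ratio 97.6, interval 26.9 to 808), and 0 and 15 in cluster 7. Rises were also seen for the semaphorin gene Sema3d (3.79, with 1 and 46 UMIs in cluster 7), the citrullinating enzyme gene Padi2 (3.66, cluster 7 3.09) and Thy1 (4.23 to 42.2 CPM, 3.40, cluster 7 3.50). In cluster 7 Cd48 rose by 2.03 and Cd244a stood at 1.73 (edgeR adjusted p = 0.060). The matrix protein gene Sparc (5.02) and the receptor phosphatase gene Ptprf (3.70) rose in the class and were too low to test in cluster 7. Gkn3, a gastrokine gene expressed in stem cells, had 542 UMIs in WT (48.4 CPM) and 0 in Tg, at least 635-fold lower with a floor of 3 counts over the group, and 540 and 0 UMIs in cluster 7. BC023719 was at least 174-fold lower by the same floor. The falls of Sbspon (-6.68, cluster 7 -3.56), the intermediate filament gene Synm (-6.53, with 177 and 0 UMIs in cluster 7), the dynamin gene Dnm3 (-6.36, cluster 7 -3.74), Egr3 (-6.67, 196 and 1 UMIs in cluster 7) and Lbhd2 (-5.95, 118 and 3 UMIs in cluster 7) had the same direction in cluster 7.

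The non-classical histocompatibility gene H2-T3 (32.8 to 0.432 CPM, -6.13, cluster 7 -3.53), the guanylate-binding protein gene Gbp4 (-5.97, cluster 7 -2.72) and the olfactory receptor gene Olfr65 (-6.05, cluster 7 -2.62) fell. Such genes have close relatives, and their values are uncertain for that reason. edgeR called 7520 of 13151 genes in the class, 3753 higher and 3767 lower (3011 and 4238 when scaled by library totals), with 801 rises and 1617 falls of more than 2-fold. The genes of largest change named in the class had edgeR adjusted p of 1.7e-31 or lower. The WT and Tg libraries did not overlap for 77.6% of tested genes, where chance gives 33.3%. In cluster 7 alone edgeR called 1348 of 11122 genes (621 higher, 727 lower), of which 1100 were also called in the class and 1026 in the same direction. The 2 comparisons share most of their WT cells, so this agreement is not independent.

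**Figure D3:**
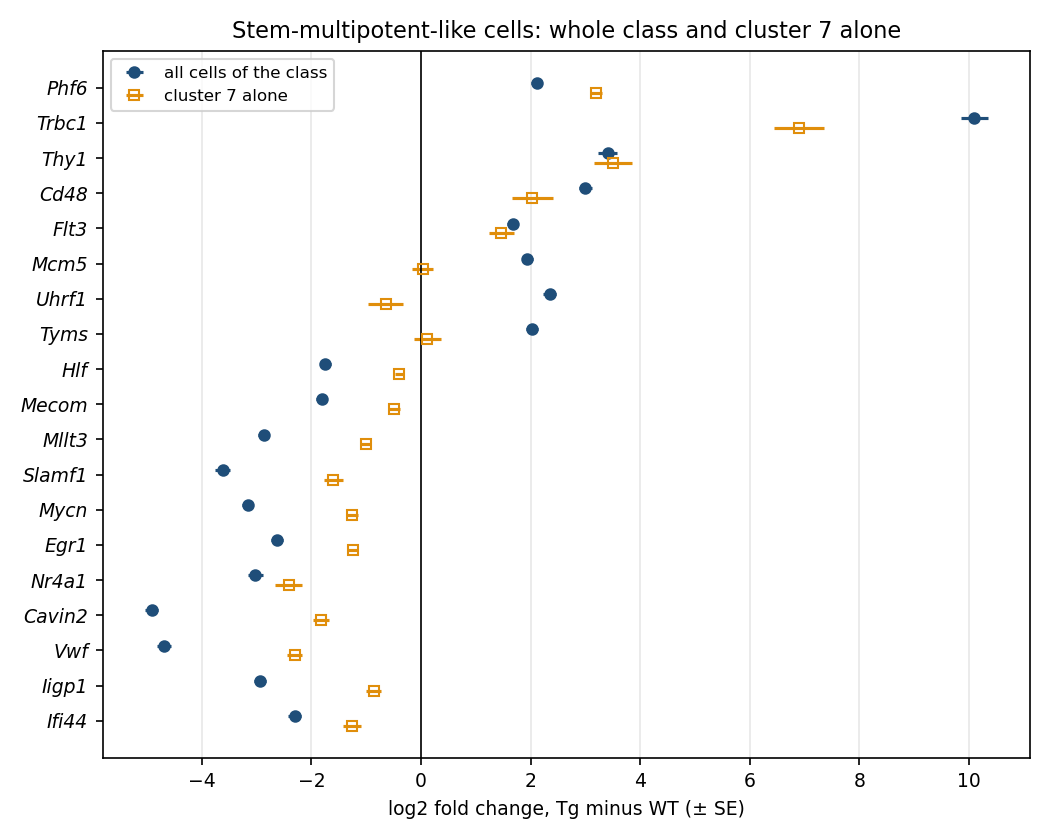
Log2 difference Tg minus WT (horizontal axis, ± SE) of genes (vertical axis) in all stem-multipotent-like cells and in cluster 7 alone, which held most WT cells and a minority of Tg cells of the class. Trbc1 had 2 UMIs in WT cells, Slamf1 was -3.62 in the class and -1.60 in cluster 7, and Uhrf1 was 2.35 and -0.64.

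Members of the S phase list rose for 41 of 41 in the class (41 and 0 over the list alone, median 1.47, camera adjusted p = 3.0e-39, or 0.27 with an estimated correlation). In cluster 7 alone the S phase median was -0.01 (camera adjusted p = 0.80), with Uhrf1 at -0.64, Mcm5 at 0.03 and Tyms at 0.11. Quiescence and self-renewal genes fell for 25 of 30 and rose for 1 (1 and 25 over the list alone, median -1.07, camera adjusted p = 2.5e-22, or 0.31 with an estimated correlation). The rise was Cdkn1a (1.06). In cluster 7 the list had 1 rise and 11 falls (1 and 13 over the list alone, median -0.24, camera adjusted p = 5.3e-08, or 0.24 with an estimated correlation). Slamf1 stood at -1.60, Egr1 at -1.24, Fgd5 at -1.24, Mllt3 at -1.01, Mecom at -0.49 and Hlf at -0.40, while Procr (-0.33, edgeR adjusted p = 0.075) did not pass. Platelet genes, which mark stem cells biased to megakaryocytes, fell for 16 of 21 and rose for 3 (3 and 16 over the list alone, median -1.06, camera adjusted p = 1.0e-12, or 0.27 with an estimated correlation). Falls included Cavin2 (-4.92, cluster 7 -1.82), Vwf (-4.69, cluster 7 -2.31), Thbs1 (-3.34) and Clec1b (-2.86), while F2rl2 (1.11) and Itga2b (0.62) rose.

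Immediate early genes, induced by growth factors and by handling stress, fell for 21 of 25 and rose for 3 (3 and 21 over the list alone, median -1.03, camera adjusted p = 1.3e-11, or 0.27 with an estimated correlation). Nr4a1 stood at -2.42 and Nr4a2 at -2.31 in cluster 7. The rises were Hspa1a, Hspa1b and Fosb (0.77). Interferon-response genes fell for 30 of 41 and rose for 2, Gbp3 and Oasl1 (2 and 30 over the list alone, median -0.64, camera adjusted p = 1.2e-07, or 0.31 with an estimated correlation). Iigp1 stood at -2.94 (cluster 7 -0.86), Ifit3 at -2.76 and Ifi44 at -2.31 (cluster 7 -1.25). Oxidative phosphorylation genes rose for 58 of 74 and fell for 1, Uqcrh (-0.28) (60 and 1 over the list alone, median 0.43, camera adjusted p = 3.2e-08, or 0.62 with an estimated correlation). Cycs (1.15), Cox5a (1.10) and Sdhd (1.04) led. Ribosome biogenesis genes rose for 36 of 38 and fell for 0 (36 and 0 over the list alone, median 0.51, camera adjusted p = 3.0e-07, or 0.31 with an estimated correlation). Rrp12 (1.11), Bop1 (1.09), Nhp2 (1.08) and Mrto4 (1.04) led. The oxidative phosphorylation median was -0.067 in cluster 7 (camera adjusted p = 0.087).

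Leukaemia-associated factors moved both ways: Mycn (-3.17, cluster 7 -1.26), Gata3 (-1.996, cluster 7 -0.69) and Nkx2-3 (-1.53, cluster 7 -0.51) fell, while the receptor kinase gene Flt3 (1.67, cluster 7 1.47) and the cyclin-dependent kinase gene Cdk6 (1.26, cluster 7 1.20) rose. Cebpa (1.78) and Myc (0.86) rose in the class and did not pass in cluster 7 (0.84 and 0.29). The list had 6 rises and 17 falls among 25 (6 and 17 over the list alone, median -0.36, camera adjusted p = 0.0069, or 0.31 with an estimated correlation). Of the nucleosome remodelling complex and Phf6 partners, Phf6, Mbd3 (0.74), Rbbp4 (0.63) and Mta3 (0.57) rose and Cdc73 (-0.41) and Chd4 (-0.26) fell. The list had 15 rises and 2 falls among 21 (15 and 2 over the list alone, median 0.34, camera adjusted p = 0.0071, or 0.31 with an estimated correlation).

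Among granule genes in the class, Camp (2.94 to 0.0509 CPM), S100a9 (-4.40), S100a8 (-4.27) and Wfdc21 (-2.37) fell and the lipocalin gene Lcn2 (3.27) and the chemokine receptor gene Cxcr2 (1.44) rose. The secondary granule list had 4 rises and 4 falls among 9 (4 and 4 over the list alone), with a median of -0.00 and a mean of -1.15 (camera adjusted p = 0.012, downward, or 0.31 with an estimated correlation). The primary granule genes Nkg7 (1.74), Ctsg (1.46) and Prss57 (1.37) rose and Fcnb (-2.85) and Elane (-1.55) fell. Of 13 members 7 rose and 2 fell (7 and 2 over the list alone, median 0.71, camera adjusted p = 0.023, or 0.31 with an estimated correlation). In cluster 7 the median was 0.031 and the test ran downward (camera adjusted p = 0.37). Levels were not corrected for free RNA in the droplets. WT Camp stood at 1.12 to 1.85 CPM in the erythroid-, basophil-mast-, megakaryocyte-, monocyte- and lymphoid-progenitor-like classes and at 215 CPM in granulocyte-progenitor-like cells. WT Elane stood at 205 CPM in stem-multipotent-like, 107 in erythroid-like, 130 in megakaryocyte-like, 169 in lymphoid-progenitor-like and 15913 CPM in granulocyte-progenitor-like cells. The falls of granule genes are therefore not assigned to the stem-multipotent-like cells themselves. Lymphoid priming genes such as Dntt (1.69), Flt3 and Satb1 (1.33) rose. The list had 5 rises and 2 falls of 13 (5 and 2 over the list alone, median 0.50, camera adjusted p = 0.031, or 0.31 with an estimated correlation). In cluster 7 Satb1 stood at -0.31 (edgeR adjusted p = 0.65), Dntt had 15 and 2 UMIs, and the list median was -0.0032 (camera adjusted p = 0.0504). Dntt stood at -0.17 in the clusters made without changed genes. Heat shock and unfolded protein response genes had 13 rises and 2 falls among 24 (13 and 2 over the list alone, median 0.27, camera adjusted p = 0.036, or 0.32 with an estimated correlation). Hspa1a stood at 0.179 and 6.46 CPM, Hspa1b at a log2 change of 3.05, Sdf2l1 at 1.27 and Trib3 at -2.10. In cluster 7 the direction turned: 0 rose and 4 fell of 22 (0 and 5 over the list alone, median -0.23, camera adjusted p = 0.013, or 0.33 with an estimated correlation), with Sdf2l1 at -0.67 (edgeR adjusted p = 0.14) and Hspa1a and Hspa1b too low to test.

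Of the other lists that passed in the class, medians in cluster 7 were -0.19 for interferon-response genes (camera adjusted p = 0.0021, or 0.42 with an estimated correlation), -0.16 for immediate early genes (adjusted p = 3.4e-04, or 0.24), -0.19 for platelet genes (adjusted p = 1.3e-05, or 0.24) and -2.43 for secondary granule genes (adjusted p = 3.8e-04, or 0.24). They were 0.045 for ribosome biogenesis (camera adjusted p = 0.96), -0.14 for leukaemia-associated factors (adjusted p = 0.0504) and 0.0998 for the nucleosome remodelling complex and Phf6 partners (adjusted p = 0.015, or 0.34 with an estimated correlation). Markers of other cell types moved in the class too. Rises and falls were 5 and 1 of 8 for lymphoid (5 and 1 over the list alone, camera adjusted p = 7.1e-05), 11 and 5 of 20 for monocyte (11 and 5, adjusted p = 0.011), 10 and 2 of 17 for basophil-mast (10 and 2, adjusted p = 0.0078), 5 and 16 of 23 for megakaryocyte (5 and 16, adjusted p = 6.1e-12) and 5 and 20 of 31 for erythroid markers (6 and 20, adjusted p = 7.6e-06). They were 0 and 3 of 3 for stroma (0 and 3, adjusted p = 4.5e-04) and 0 and 5 of 6 for macrophage markers (0 and 5, adjusted p = 0.047). With an estimated correlation none of these passed (adjusted p 0.13 or higher).

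Lists that did not pass camera in the class included G2M phase (22 rises and 7 falls of 51, camera adjusted p = 0.083), which passed upward without the cycling cluster 16 (46 and 1 of 51, camera adjusted p = 4.6e-13, or 0.26 with an estimated correlation). Glycolysis (9 and 5 of 16, camera adjusted p = 0.069), histones (3 and 7 of 16, adjusted p = 0.15), ribosomal proteins (22 and 7 of 77, adjusted p = 0.20), cytokine receptor targets (9 and 14 of 25, adjusted p = 0.21) and antigen presentation (5 and 5 of 19, adjusted p = 0.28) did not pass. Nor did inflammatory genes (4 and 8 of 23, camera adjusted p = 0.34), mitochondrially encoded transcripts (1 and 3 of 13, adjusted p = 0.41), Polycomb genes (12 and 8 of 38, adjusted p = 0.52) or p53 targets (8 and 10 of 25, adjusted p = 0.65). Median and mean differed in sign for heme genes (6 and 4 of 16, 0.14 and -0.34, camera adjusted p = 0.20, upward) and cholesterol synthesis (6 and 7 of 23, 0.09 and -0.11, camera adjusted p = 0.86). Adjusted over the list alone, these counts were the same except for ribosomal proteins (20 and 7) and p53 targets (8 and 11). In cluster 7 alone, histones fell for 9 of 12 and rose for 0 (0 and 11 over the list alone, median -0.68, camera adjusted p = 9.2e-07, or 0.24 with an estimated correlation).

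**Figure D4:**
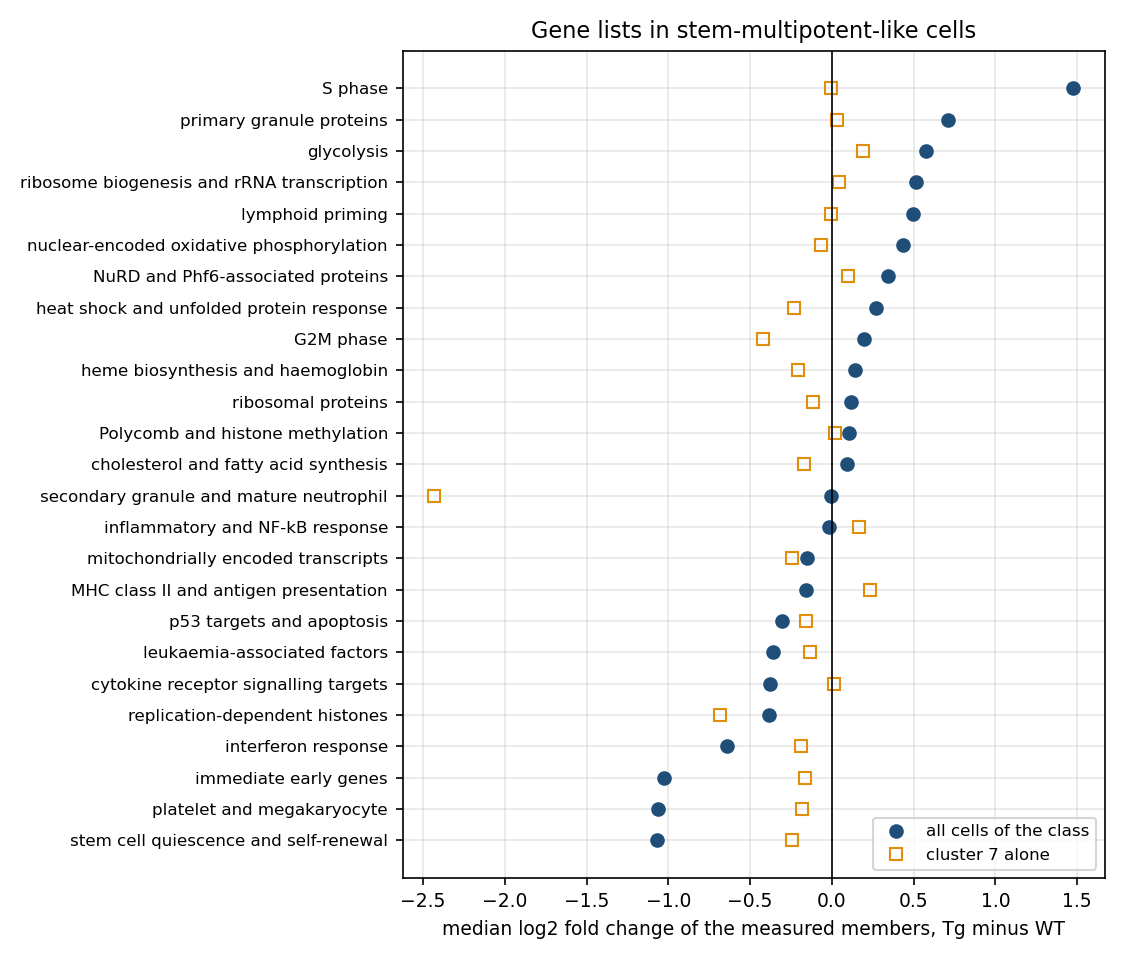
Median log2 difference Tg minus WT (horizontal axis) of each gene list (vertical axis) in all stem-multipotent-like cells and in cluster 7 alone. The S phase median was 1.47 in the class and -0.01 in cluster 7, and the quiescence median was -1.07 and -0.24.

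In granulocyte-progenitor-like cells, S100a8 fell from 5014 to 373 CPM (log2 -3.77, SE 0.12) and Fcnb from 170 to 14.2 CPM (-3.61). The chaperone genes Hspa1a (6.32) and Hspa1b (4.97) and the interferon-induced membrane protein gene Ifitm1 (14.5 to 253 CPM, 4.10) rose. Heat shock and unfolded protein response genes rose for 16 of 25 and fell for 0 (16 and 0 over the list alone, camera adjusted p = 7.2e-11, or 0.31 with an estimated correlation). Ribosome biogenesis genes rose for 29 of 38 (30 over the list alone, adjusted p = 8.3e-07, or 0.31 with an estimated correlation) and cholesterol synthesis genes for 16 of 22 (16 over the list alone, adjusted p = 1.9e-06, or 0.31 with an estimated correlation). Interferon-response genes fell for 31 of 42 (31 over the list alone, camera adjusted p = 3.4e-08, or 0.31 with an estimated correlation). BC023719 had 919 UMIs in WT and 1 in Tg (ratio 1255, interval 225 to 49604). edgeR called 6146 of 12696 genes, 3132 higher and 3014 lower (3265 and 2556 when scaled by library totals), without overlap for 72.5% where chance gives 33.3%. Most cells of the class came from cluster 5 in WT (52.6 and 53.9%) and from cluster 1 in Tg (61.3 and 56.0%), and the lowered S100a8 and Fcnb are among the genes that define cluster 5. Granulocyte markers fell for 15 of 28 and rose for 2 (2 and 15 over the list alone, camera adjusted p = 1.2e-12, or 0.501 with an estimated correlation) and macrophage markers fell for 5 of 6 (5 over the list alone, adjusted p = 4.3e-06, or 0.44). B-lineage markers fell for 3 of 8 and rose for 1 (1 and 3, adjusted p = 0.017, or 0.501) and T-NK markers rose for 2 of 5 (2, adjusted p = 0.017, or 0.501). Trbc1, which rose in every class, was among those T-NK rises.

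Monocyte-like cells of Tg mice expressed Ifi202b, an interferon-inducible DNA-binding protein gene, with 975 UMIs (18.6 CPM) against 0 in WT, at least 295-fold higher with a floor of 3 counts over the group. Hspa1a rose from 1.11 to 44.5 CPM (5.28) and Dntt, a lymphoid DNA polymerase gene, from 0.440 to 10.1 CPM (4.50). S100a8 (47.2 to 3.70 CPM, -3.63) and Fnbp1l, a membrane-curving protein gene (29.0 to 2.61 CPM, -3.50), fell, and BC023719 was at least 243-fold lower. Ribosome biogenesis genes rose for 31 of 38 (31 over the list alone, camera adjusted p = 4.2e-08, or 0.41 with an estimated correlation) and interferon-response genes fell for 24 of 39 (24 over the list alone, adjusted p = 6.2e-06, or 0.41 with an estimated correlation). edgeR called 5578 of 12247 genes, 2882 higher and 2696 lower, without overlap for 72.0% where chance gives 33.3%. Granulocyte markers fell for 17 of 28 and rose for 4 (5 and 17 over the list alone, camera adjusted p = 3.9e-11, or 0.62 with an estimated correlation), monocyte markers fell for 11 of 23 and rose for 6 (6 and 12, adjusted p = 8.0e-04, or 0.33) and lymphoid markers rose for 4 of 7 (5 over the list alone, adjusted p = 1.5e-07, or 0.33). Cluster 2 held 98.5 and 99.1% of the class in WT and cluster 4 held 98.3 and 98.8% in Tg.

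Erythroid-like cells of Tg mice had 0 UMIs of Mst1r, the gene of the receptor kinase Ron, against 677 in WT (20.1 CPM), at least 99.6-fold lower. Trbc1 (0.151 to 10.7 CPM, 6.01), Hspa1a (4.78) and Hspa1b (3.61) rose, S100a8 fell (-4.40) and BC023719 was at least 130-fold lower. G2M genes fell for 36 of 51 (41 over the list alone, camera adjusted p = 3.6e-10, or 0.27 with an estimated correlation), ribosome biogenesis genes for 30 of 38 (30 over the list alone, adjusted p = 5.3e-10, or 0.27 with an estimated correlation) and S phase genes for 23 of 41 (24 over the list alone, adjusted p = 1.0e-04, or 0.27 with an estimated correlation). Immediate early genes rose for 15 of 21 (17 over the list alone, camera adjusted p = 2.9e-12, or 0.27 with an estimated correlation) and quiescence genes for 16 of 25 (17 over the list alone, adjusted p = 6.9e-07, or 0.27 with an estimated correlation). Markers of other cell types rose with them, basophil-mast for 9 of 14 (9 over the list alone, camera adjusted p = 2.6e-10, or 0.18 with an estimated correlation), megakaryocyte for 12 of 17 (12, adjusted p = 2.1e-06, or 0.18) and stem for 12 of 21 (12, adjusted p = 2.1e-06, or 0.24). Erythroid markers fell for 18 of 45 and rose for 5 (8 and 19 over the list alone, adjusted p = 0.016, or 0.26), and granulocyte markers fell for 11 of 24 and rose for 5 (5 and 11, adjusted p = 0.044, or 0.26). T-NK markers rose for 2 of 3 (2, adjusted p = 2.8e-05, or 0.24), with Trbc1 among them. edgeR called 4394 of 11380 genes, 2257 higher and 2137 lower, without overlap for 68.1% where chance gives 33.3%. Of the called genes 51.4% were higher, or 65.9% when scaled by library totals and 39.1% with DESeq2. Cluster 11 held 53.6 and 50.5% of the class in WT and 70.9 and 71.9% in Tg, and median depth was 19592 and 20085 UMIs per cell in WT and 9231 and 9106 in Tg.

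In lymphoid-progenitor-like cells, lymphoid priming genes rose for 12 of 17 and fell for 0 (12 and 0 over the list alone, camera adjusted p = 1.1e-22, or 0.13 with an estimated correlation). Ly6d, a marker of B-lineage commitment, rose from 1.38 to 29.2 CPM (4.41), but stood at -0.027 in the clusters made without changed genes. Trbc2 (1.88 to 31.5 CPM, 4.11) and Hspa1b (0.331 to 18.7 CPM, 5.70) rose. H2-T3, the protocadherin gene Pcdh7 and BC023719 had 0 UMIs in Tg, at least 20.3-fold, 19.9-fold and 19.5-fold lower. Quiescence genes fell for 21 of 29 (21 over the list alone, camera adjusted p = 8.1e-21, or 0.13 with an estimated correlation) and immediate early genes for 16 of 22 (16 over the list alone, adjusted p = 1.4e-10, or 0.13 with an estimated correlation). Stem markers fell with them for 19 of 25 and rose for 2 (2 and 20 over the list alone, camera adjusted p = 3.9e-23, or 0.061 with an estimated correlation) and megakaryocyte markers fell for 9 of 13 (10 over the list alone, adjusted p = 1.2e-09, or 0.061). Monocyte markers rose for 14 of 19 and fell for 2 (15 and 2, adjusted p = 1.5e-14, or 0.061) and lymphoid markers rose for 9 of 11 (9, adjusted p = 5.4e-19, or 0.061). Dendritic (8 rises and 4 falls of 15, adjusted p = 8.7e-06, or 0.15), B-lineage (3 and 1 of 8, adjusted p = 1.4e-04, or 0.19) and T-NK markers (4 and 0 of 9, adjusted p = 9.6e-09, or 0.061) also passed upward. Basophil-mast (1 and 5 of 8, adjusted p = 1.4e-04, or 0.23), erythroid (3 and 10 of 20, adjusted p = 0.031, or 0.19) and granulocyte markers (6 and 7 of 22, adjusted p = 0.039, or 0.28) passed downward. Over the list alone these were 8 and 5, 4 and 1, 4 and 1, 1 and 5, 4 and 11 and 7 and 8. The T-NK rises included Trbc1 and Trbc2. edgeR called 2935 of 11178 genes, 1486 higher and 1449 lower, without overlap for 62.3% where chance gives 33.3%. Of the called genes 50.6% were higher, or 39.5% when scaled by library totals and 55.1% with DESeq2. The class was 1 cluster in both genotypes.

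Megakaryocyte-like cells of Tg mice had more platelet gene transcripts, 13 rises and 1 fall of 23 (15 and 1 over the list alone, camera adjusted p = 2.7e-08, or 0.47 with an estimated correlation). Quiescence genes fell for 15 of 30 (18 over the list alone, adjusted p = 1.8e-12, or 0.30 with an estimated correlation). Stem markers fell for 15 of 29 and rose for 3 (3 and 18 over the list alone, camera adjusted p = 8.0e-11, or 0.26 with an estimated correlation), and basophil-mast markers rose for 5 of 8 (6 over the list alone, adjusted p = 1.1e-07, or 0.26). Megakaryocyte markers rose for 14 of 25 and fell for 3 (16 and 3, adjusted p = 5.9e-08, or 0.26), while granulocyte (3 rises and 7 falls of 20, 4 and 7 over the list alone, adjusted p = 0.0017, or 0.26) and erythroid markers (6 and 8 of 28, 8 and 8 over the list alone, adjusted p = 0.0088, or 0.26) passed downward. Atp6v0e2, a proton pump subunit gene, had 1 UMI in WT and 114 in Tg (ratio 119, interval 20.9 to 4728), and Trbc1 had 3 and 239 (ratio 82.9, interval 28.0 to 405). Hspa1a rose (5.80). Gkn3 had 337 and 3 UMIs (ratio WT over Tg 108, interval 36.6 to 526) and H2-T3 225 and 1 (ratio 216, interval 38.4 to 8575), and BC023719 was at least 58.0-fold lower. edgeR called 2373 of 11313 genes, 1172 higher and 1201 lower, without overlap for 58.2% where chance gives 33.3%.

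In basophil-mast-like cells, Hspa1b, Hspa1a and the flippase gene Atp8b5 had 0 UMIs in WT and were at least 40.8-fold, 25.7-fold and 19.3-fold higher in Tg. S100a8 fell from 56.1 to 1.66 CPM (-5.06) and Gimap6 from 16.6 to 0.889 CPM (-4.14), and BC023719 was at least 42.0-fold lower. Histone transcripts fell for 13 of 15 (13 over the list alone, camera adjusted p = 1.4e-31, or 0.15 with an estimated correlation). T-NK markers passed upward (3 rises and 1 fall of 5, 3 and 2 over the list alone, camera adjusted p = 1.6e-24, or 0.095 with an estimated correlation), as did eosinophil (1 and 0 of 3, 1 and 0 over the list alone, adjusted p = 0.0023, or 0.32) and megakaryocyte markers (3 and 0 of 12, 4 and 0 over the list alone, adjusted p = 0.029, or 0.32). The T-NK list holds Trbc1 (9.81 to 237 CPM) and Trbc2 (0.277 to 111 CPM), while Cd3e, Cd3g and Trac had 0 UMIs in the class. Its rise is therefore not read as T-cell identity. Lymphoid markers fell for 3 of 7 (4 over the list alone, adjusted p = 0.0092, or 0.32). edgeR called 600 of 10092 genes, 264 higher and 336 lower, without overlap for 47.7% where chance gives 33.3%. Histone, interferon-response and secondary granule genes passed camera downward in each of these 6 classes, and with an estimated correlation in none. The secondary granule list holds S100a8 and S100a9, for which free RNA in the droplets was not excluded outside the granulocyte lineage. Levels summed over a class do not separate its make-up from changes within its cells. For Phf6 and the genes named by size of change in these classes, edgeR adjusted p was 8.4e-10 or lower. Of the 25 lists, 11 passed in granulocyte-progenitor-like, 14 in monocyte-like, 14 in erythroid-like, 16 in lymphoid-progenitor-like, 12 in megakaryocyte-like and 9 in basophil-mast-like cells. With an estimated correlation 0 passed in any of them (adjusted p 0.13 or higher). Of 9648 genes tested in all 7 classes, 96 changed in the same direction in all 7.

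The stem-multipotent-like and granulocyte-progenitor-like classes differed in how far genes moved. Cd48 rose by 2.43 more (SE 0.09, edgeR adjusted p = 1.2e-158), Cd244a by 2.38 more (SE 0.21, 4.4e-27), Padi2 by 2.29 more (SE 0.53, 8.0e-05) and Phf6 by 1.32 more (SE 0.09, 1.4e-45) in stem-multipotent-like cells. Ifitm1, already at 913 CPM in WT stem-multipotent-like cells and 1560 CPM in Tg, rose by less there than in granulocyte-progenitor-like cells (difference -3.19, SE 0.06), as did Hspa1b (-1.87, SE 0.54, edgeR adjusted p = 0.0023). Trbc1 (4.87, SE 1.08, edgeR adjusted p = 4.8e-05) and Trbc2 (4.95, SE 1.35, 0.0010) rose by more in stem-multipotent-like cells, and the term for Synm was -6.47 (SE 1.51, 9.7e-05). Synm stood at 0.0485 and 0.0464 CPM in granulocyte-progenitor-like cells, and Trbc2 at 0.0579 and 0.213 CPM, too low for a change to be tested there. Trbc1 and Trbc2 had 2 UMIs each in WT stem-multipotent-like cells, which makes their size imprecise. Hspa1a (-1.09, edgeR adjusted p = 0.51), S100a8 (-0.45, adjusted p = 0.065) and Thy1 (0.33, adjusted p = 0.57) did not pass this test. Both classes were filled from different clusters by genotype (7 and 0 for stem-multipotent-like, 5 and 1 for granulocyte-progenitor-like cells), so the interaction also holds what differs between those clusters. With the library as a term, edgeR's test of the interaction called 5813 of 14221 genes, 3556 with a higher and 2257 with a lower value in stem-multipotent-like cells. The excess of higher values was smaller with DESeq2, where 1524 were higher and 1358 lower. It was not kept without Tg 1, where the median log2 difference was -0.038 against 0.057 with all libraries.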

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

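The tests in this part were chosen only after the results were seen, except the interaction test and the test of near-identical genes over the last 500 bases of transcripts, which were set before the data were examined.

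The interaction test found 5813 genes whose difference between genotypes was not the same in stem-multipotent-like and granulocyte-progenitor-like cells, and 2882 with DESeq2. Both classes were filled from different clusters by genotype, so these differences include differences between clusters. Among the named genes these were Phf6 (1.32, stem-multipotent-like minus granulocyte-progenitor-like, log2), Cd48 (2.43), Cd244a (2.38), Padi2 (2.29), Trbc1 (4.87), Trbc2 (4.95), Hspa1b (-1.87), Ifitm1 (-3.19) and Synm (-6.47). Trbc2 and Synm were too low to test in granulocyte-progenitor-like cells alone. In each of these the planned test of the difference between classes had an adjusted p under 0.05.

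Cells outside the named classes were common in Tg libraries. A cluster led by Ifitm1, Cpa3, Tespa1 and Cd34 held 13.1% of Tg and 0.199% of WT cells, and a cluster led by Apoe, Mfsd2b and F2r held 6.38% and 3.30%. A small cluster led by Gngt2, Clec4a3 and Apoc2 held 0.176% and 0.0161%, with 29 cells at 0.155 of the median depth of their libraries. These clusters had no class by the naming rule and were not tested. In clusters made without the changed genes, a cluster with no class held 7.82 and 7.71% of the Tg libraries against 1.12 and 0.991% of the WT libraries. Another held 10.4 and 11.4% against 3.83 and 3.08%. New clusters took the class that most of their cells had before, so this is not an independent check.

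The chaperone genes Hspa1a and Hspa1b, S100a8, Trbc1 and BC023719 were among 23 genes that moved over 2-fold in the same direction in all 7 classes, 12 higher and 11 lower. Of the 23, 4 lay on chromosome 17, where 1.27 were expected. At most 3 of the 23 lay within 5 Mb, on chromosome 17 from 34956436 to 36117121. That number was reached by 666 of 10000 random draws of 23 genes (95th percentile 3). A single segment of that size did not account for the whole set, but such a segment behind part of it was not excluded. H2-T3, which is not among the 23 and not in that count, starts at 36185572, close to BC023719. It had 365 UMIs in WT and 17 in Tg stem-multipotent-like cells, and 225 and 1 in megakaryocyte-like cells. A near-identical stretch in another gene was found within the last 500 bases for 26.1% of the 23 genes, above the 95th percentile of 17.4% in 1000 draws. Reads shared between such genes make the values of those 6 uncertain, which include Hist1h2ab, Ly6c2 and BC023719. The search used the same reference transcripts for both genotypes, so similarity alone does not give a difference between them. Searched over all bases of the transcripts of the 23 genes, 14 had such a stretch and 9 had none. Among the 14 were Hspa1a, Hspa1b, Trbc1 and Csf2rb2, which had no such stretch within the last 500 bases. For the set as a whole shared reads cannot be told apart from other causes. Ifi202b, which C57BL/6 mice do not express, had 1563 UMIs in Tg (705 and 858) and 0 in WT, so a strain difference between the mice and the genotype cannot be told apart. At this gene the Tg counts go against the C57BL/6 strain given in the labels. With strain open, none of the 23 genes is called an effect of the Phf6 label.

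S100a8 in granulocyte-progenitor-like cells fell by 3.77 (log2, SE 0.12) within the class. Fewer late-stage precursors within the class cannot be told apart from a lower transcript level per cell: the other 11 late granule genes had a median of -1.22, but 4 fell, 2 rose and the range ran from -3.86 to 1.99 (Lcn2). Outside the granulocyte lineage, S100a8 stood at 32.6 to 68.4 CPM in WT, and in 9 of 12 pairs of class and library the ratio of S100a8 to S100a9 held that of the whole library. That count is consistent with free S100a8 and S100a9 RNA in the droplets as the source of the signal in those classes. Both monocyte-like pairs and the lymphoid-progenitor-like pair of WT 1 lay outside.

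Trbc1 and Trbc2 in Tg stem-multipotent-like cells came with few other T-cell transcripts. Cd3d had 13 UMIs, and Cd3e, Cd3g and Trac had 0, where 14080 were implied by the ratio in T-NK-like cells (upper limit of the count 3.69), so T cells in the class were excluded. The Trbc1 level of the class was at least 11.4 times the median of the other classes in each Tg library (highest 11.8, other classes 1.28 to 253 CPM), so free Trbc1 RNA was excluded as well. The rise was not particular to this class. Trbc1 stood at 222 and 253 CPM in Tg basophil-mast-like cells, 182 and 209 in stem-multipotent-like cells and 120 and 142 in lymphoid-progenitor-like cells. Mean Trbc2 in Tg was 111 CPM in basophil-mast-like and 17.5 CPM in stem-multipotent-like cells. Trbc1 is also among the 23 genes above, for which a strain difference cannot be told apart from the genotype, so the rise is not called an effect of the Phf6 label.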

How the results depend on the processing

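The tests with classes after centring, clusters without changed genes, another clustering seed, without the cycling cluster and with cluster 7 alone were chosen only after the results were seen; the others were planned.

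DESeq2 called fewer genes in basophil-mast-like (152), erythroid-like (2271), lymphoid-progenitor-like (934), megakaryocyte-like (694) and monocyte-like cells (3352), and 2882 in the interaction test (1524 higher and 1358 lower). Without Tg 1 the interaction test gave 2442 higher and 2477 lower. In lymphoid-progenitor-like cells edgeR called 1668 genes with no doublet removal, 1417 with stricter cells, 807 with classes after centring and 1182 with clusters without changed genes. Another clustering seed gave 911 genes in basophil-mast-like cells, and cluster 7 alone 1348 in stem-multipotent-like cells. Counts of genes held within 1.5 times in 92 of 119 alternatives.

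Leaving out 1 library left the lone library of its genotype to be assumed to vary like the others. Counts then ran from 3776 to 9540 over all cells (3776 without WT 1, 3913 without WT 2), 210 to 1046 in basophil-mast-like cells (210 without WT 1, 220 without WT 2, 1046 without Tg 1) and 2507 to 4425 in erythroid-like cells (2507 without either WT library). They ran from 3189 to 7560 in granulocyte-progenitor-like cells (3189 without WT 1, 3483 without WT 2), 1411 to 2642 in lymphoid-progenitor-like cells (1411 without WT 1, 1577 without WT 2), 958 to 2878 in megakaryocyte-like cells (958 without WT 1, 1150 without WT 2) and 3313 to 6658 in monocyte-like cells (3313 without WT 1, 3411 without WT 2). Stem-multipotent-like cells gave 5220 to 7528 and the interaction 3967 to 5025. Gene levels of the Tg libraries differed by 6.83 times the noise of sampling cells, and those of the WT libraries by 2.17 times. Whether this gap in spread is the cause was not tested. Phf6 stayed between 1.44 and 1.71, and all 12 of its alternatives kept the direction and the call.

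The fall of dendritic-like cells was weaker and did not pass at resolution 0.6 (-0.37), with centred components (-0.37), with clusters without changed genes (-0.33) and with TMM factors over classes (-0.36). Without any 1 library it did not pass either, but the fold of -0.75 to -0.48 lay around the -0.62 of all libraries. The stem-multipotent-like rise was 0.39 with centred components, 0.60 with no doublet removal and 0.85 with stricter cells, and the lymphoid-progenitor-like fall -0.99, -3.78 and -3.46, all with the same call. The monocyte-like fall did not pass with TMM factors (-0.19) and without WT 2 (-0.40), with a range of -0.56 to -0.35 over libraries left out. Granulocyte-progenitor-like cells passed as lower at resolutions 0.6 (-0.44) and 1.5 (-0.15), with centred components (-0.62), with another seed (-0.28) and without Tg 2 (-0.28; range to -0.089). Megakaryocyte-like cells turned to a rise at resolutions 0.6 (0.30) and 1.5 (0.31), with centred components (0.26), no doublet removal (0.93), stricter cells (0.65) and another seed (0.92). With clusters without changed genes the eosinophil-like rise reversed (-0.29) and the stem-multipotent-like rise did not pass (0.23). At resolution 0.6 no T-NK-like cluster formed. Of 129 share alternatives 105 gave the same call.

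With an estimated correlation camera passed 0 of 25 lists over all cells and 0 in each of the 7 classes. Over all cells and in stem-multipotent-like cells 1 and 3 of them had an unadjusted p under 0.05, while fry passed 6 and 15. These were not all the lists that camera passed. Over all cells fry passed inflammatory genes (fry adjusted p = 0.038) and cytokine receptor targets (0.015), and it did not pass histones, glycolysis, ribosome biogenesis or quiescence genes. In the simulated data the estimated correlation found 0 of 1 altered list. In cluster 7 alone the median or the test reversed for G2M phase (-0.42), ribosomal proteins (-0.11), oxidative phosphorylation (-0.067), heat shock (-0.23), primary granule (0.031, tested downward) and antigen presentation (0.23). Lymphoid priming reversed over all cells without WT 1 (-0.44, range to -0.030) and, in the stem-multipotent-like class, with clusters without changed genes (0.0066). Gene list results were the same in 490 of 575 alternatives.

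Ccl5 (0.041) and Il7r (0.45) reversed over all cells with equal class shares. With clusters without changed genes Ly6d reversed in lymphoid-progenitor-like cells (-0.027), and Mpo (-0.17), H2-T23 (0.092) and Dntt (-0.17) in stem-multipotent-like cells. There, H2-T23 also reversed with no doublet removal (0.045) and stricter cells (0.016), Aurkb with stricter cells (-0.24) and Hist1h2ab without the cycling cluster (0.78). In cluster 7 alone Uhrf1 (-0.64), Cks1b (-0.13), Sdf2l1 (-0.67), Dnmt1 (-0.019), Ezh2 (-0.012), Tfrc (-0.26), Tmem14c (-0.069), Mpo (-0.51), H2-Aa (0.23), H2-T23 (0.29), Satb1 (-0.31) and Elovl6 (-0.027) reversed. Named genes kept direction and call in 3577 of 3765 alternatives.

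With the replicate number as a replicate block, edgeR called 7581 genes over all cells and 7770 in stem-multipotent-like cells, and Phf6 was 1.58. The dendritic-like fall was -0.61 and did not pass. The numbers are names: gene levels of libraries with the same number correlated by 0.0251 over 2 pairs. The interaction test already had the library as a term.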

Other observations

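The edgeR values in this part come from the planned comparison over all cells. Cd34, Camp and the clusters made without the changed genes were chosen only after the results were seen.

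Xist, the transcript of the inactive X chromosome, stood at 1758 and 1686 CPM in the WT libraries and 1695 and 1553 CPM in the Tg libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 2 UMIs in any library, so all 4 libraries came from female cells by these genes. In Tg cells, Cd34, a surface marker of progenitors, rose from 128 to 206 CPM over all cells (0.71, edgeR adjusted p = 9.3e-05). The cathelicidin gene Camp stood at 68.4 and 5.08 CPM (-3.68, edgeR adjusted p = 0.17), with a wide spread between the Tg libraries (0.990 and 9.17 CPM).

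A cluster led by Bcl2, Irf8, Ly86 and Mndal held 7.86% of WT and 0.121% of Tg cells, and one led by Serp1, Jund and Jun held 1.16% and 0.174% at 0.0899 of the median depth. Neither had a class, and neither was tested. In clusters made without the changed genes, clusters with mostly 1 genotype remained. A granulocyte-progenitor-like cluster held 0.450 and 0.666% of the WT libraries and 12.4 and 18.1% of the Tg libraries, another 17.8 and 17.9% against 1.59 and 0.602%, and one more 8.69 and 9.38% against 0.493 and 0.118%. A cluster with no class held 1.12 and 0.991% against 7.82 and 7.71%, and another, less one-sided, 3.83 and 3.08% against 10.4 and 11.4%. The share of barcodes over the mitochondrial limit was 9.68 and 6.22% in Tg libraries and 20.1 and 16.0% in WT libraries, and damage during preparation was not analysed here.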
